A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

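RNA was sequenced from cultures of the yeast Saccharomyces cerevisiae grown in chemostats. In these vessels the rate of a steady feed sets the growth rate, while a scarce nutrient limits the culture. The series title concerns the building of small chemostats for characterising many strains. The 36 libraries form 12 groups of 3, which the design text states to be biological triplicates, so the p-values rest on separate cultures as stated there. The groups fall into 3 sets. The DASGIP tagged set was grown in a 1 L vessel labelled DASGIP and carried HAP1-TAP, a strain made from CEN.PK 113-5D by fusing a purification tag to the end of the regulator Hap1p. The MC tagged set carried the same strain in vessels labelled MC, read here as mini-chemostat from the series title. The MC untagged set carried CEN.PK 113-5D itself in MC vessels. Each set held 4 limitations: nitrogen with 6% glucose (N-lim), ethanol at 0.5% (Et-lim), glucose at 0.75% (Glu-lim), and oxygen together with glucose at 1% glucose (OxGlu-lim). Sampling followed 48 to 60 h of constant culture readings, per the labels.

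RNA was extracted with an RNeasy kit and made into libraries with a stranded total RNA kit that removes ribosomal RNA, per the labels' protocols. Alignment and counting used Bowtie2, SAMtools and bedtools on genome build R64, per the submitters' processing notes, without versions. The deposited values used here are whole-number counts of reads per annotated gene, per the file headers. The counting rule and its use of strand are not given in the sources used here. Values of genes that overlap or lie antisense to each other are therefore uncertain, as are those of near-identical families (HXT6 and HXT7, TDH, PAU, histone pairs, ribosomal protein paralogs, CUP1-1, SNR7-L and SNR7-S). Build R64 describes another laboratory strain than CEN.PK, so sequence that differs between them can lower a count in every library alike. The deposited tables also hold columns the authors named CPM and mean. Each CPM value equalled the count divided by the sum of its own and all later lines (largest deviation 3.48%), with a median of 3.38 times the true CPM, and each mean column held a median. Those columns were used only for that check and not as expression.

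Each table gave 7122 gene lines that were used and 4 that were not analysed here. Of the 7122, 6681 were nuclear reading frames, 299 tRNA genes, 87 small RNA genes, 30 mitochondrially encoded, 14 rRNA and 11 other. RefSeq locus tags matched 6045 of them, and coordinates come from that R64 annotation. In 122 lines every library had 0 counts. Within the MC untagged set the 12 small RNA lines SNR70 to SNR79, SNR7-L and SNR7-S stood 2 places away from their position in N-lim in all 9 libraries of the other limitations. A search of all 12 groups used windows of 3 to 20 lines and shifts of up to 3 places. It compared each group with other groups of its limitation, so for the MC untagged set the shift was fitted to tagged libraries. The fall in the sum of squares was 256 or more in these lines and at most 6.27 elsewhere. The values were kept as deposited in the tests, the number of these lines among the strain calls is given in the report, they make up 8, 7 and 4 of the mean calls for N-lim, Et-lim and OxGlu-lim, and 2 alternatives without them or with them moved back were added after the data were seen.

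Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A single model with a mean for each of the 12 groups covered all 36 libraries, with TMM factors and the default filter on low counts, which left 6612 genes and 24 residual degrees of freedom. Reactor contrasts took MC tagged minus DASGIP tagged libraries, strain contrasts MC tagged minus MC untagged, and limitation contrasts N-lim, Et-lim or OxGlu-lim minus Glu-lim. Each was tested as a mean (over 4 limitations or 3 sets) and within each limitation or set, and F tests asked whether the reactor or strain difference varied by limitation. Fold changes are on the log2 scale with standard errors (SE). CPM values are means ± SD of 3 libraries on TMM-scaled library sizes. No batch, date or lane appears in the labels, so reactor and strain differences cannot be separated from any batch that ran with a set. Reactor and strain contrasts share the MC tagged libraries, and the 3 limitation contrasts share the Glu-lim libraries, so no overlap between contrasts that share libraries was counted.

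The design, the comparisons, the rule for naming genes, 36 lists of genes (pathways, stress programmes, cell cycle phases, cell types) and all alternatives but the 2 added ones were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 36 lists. Correlations estimated from the data and fry served as alternatives. Genes named in the text are the 6 largest and 6 smallest fold changes of each of the 5 mean contrasts, among genes past the threshold with mean log2 CPM of at least 3 and 1 sign in every contrast averaged. To these came 3 members of up to 8 lists per mean contrast, the 3 largest and 3 smallest changes within each limitation or set, the 6 smallest p-values of each F test and 28 genes chosen in advance. Further genes that took the place of displaced lines, and the split by kind of RNA, were chosen after their values were seen.

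Total counts per library ran from 10.7 to 22.5 M (mega) reads. For 36 pairs of replicates the chi-square per degree of freedom over genes with a pair sum of at least 20 lay between 5.50 and 155, so replicates differed by more than counting noise and sampling depth alone does not set the precision. The tests were tried on simulated counts with 200 changed genes. Every group was given the same spread for a gene, so the rates below do not cover groups of unequal spread. In the simulated mean reactor comparison of 6560 genes, edgeR recovered 65 of 67 genes changed 1.5-fold, 65 of 67 changed 2-fold and 65 of 66 changed 4-fold, and 3.94% of its calls were false. In the simulated strain comparison under Et-lim (6561 genes) it recovered 63 of 67, 61 of 67 and 66 of 66, with 6.40% false. In the F test of the reactor difference by limitation (6557 genes) it recovered only 28 of 67 genes changed 1.5-fold. At 2-fold it recovered 60 of 67 and at 4-fold 65 of 66. The share of false edgeR calls was 6.64% for the N-lim mean, 7.5% for Et-lim in the MC untagged set and 6.67% for the OxGlu-lim mean. With DESeq2 10.1% of calls were false in the simulated strain comparison under Et-lim. A planted list of 20 genes, all changed 2-fold in 1 direction, was found by camera in each of 7 simulated comparisons, and random lists gave p of 0.422 to 0.986. Genes were simulated independently of each other, so this cannot test the preset correlation where the genes of a list vary together.

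The alternatives tried were RLE and upper-quartile factors, no low-count filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, fits on only the libraries compared, a replicate number as a block (shared or within each set), libraries thinned to equal depth, library sizes without rRNA, tRNA and mitochondrially encoded lines, thresholds of 0.01 or of a 2-fold change, fold-change correlations on genes above log2 CPM 5, and leaving out each of the 36 libraries. Tables were joined and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Dixon's test for a divergent library was not run on these groups of 3.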

Results

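The 36 libraries held 10.7 to 22.5 M (mega) counted reads each (median 16.7 M). Group means ± SD of 3 libraries ran from 13.1 ± 2.04 M in DASGIP tagged OxGlu-lim to 21.2 ± 1.31 M in MC untagged Et-lim. Between 6724 and 6835 genes had counts in a library, and rRNA lines took at most 0.000158% of the reads. Small RNA took 11.4% to 20.2%. Mitochondrially encoded genes took 9.19% to 46.6% of a library, and their share followed the limitation: in the MC tagged set it was 11.4 ± 3.13% under N-lim, 22.8 ± 3.54% under OxGlu-lim, 33.9 ± 4.30% under Glu-lim and 34.9 ± 2.86% under Et-lim. The DASGIP tagged set ran from 10.9 ± 0.245% to 34.5 ± 3.04% and the MC untagged set from 15.9 ± 0.947% under N-lim to 43.3 ± 3.09% under Et-lim. Every library was closest to a library of its own group, and replicates correlated at r of 0.973 to 0.994 across genes. Limitation held 74.2% of the variance of log2 CPM, set 6.88%, their combination 8.40% and replicates 10.5%.

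**Figure D1:**
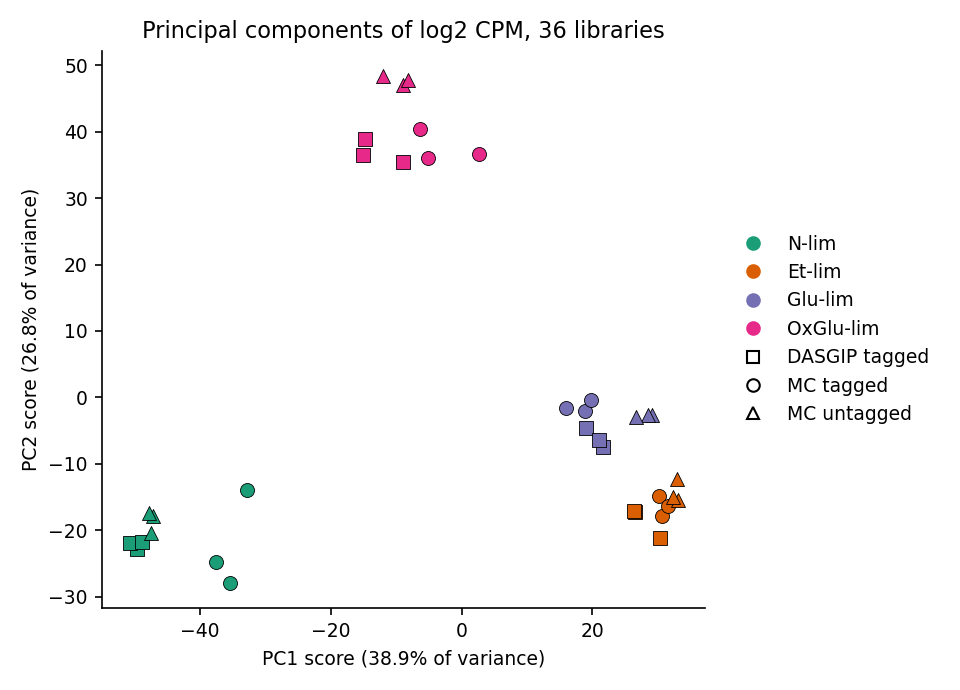
First principal component (38.9% of variance, x axis) against the second (26.8%, y axis) of log2 CPM in the 36 libraries, each a point, with colour for the limitation and shape for the set. N-lim and OxGlu-lim libraries lie apart from the others, while some Glu-lim and Et-lim libraries lie as close to each other as sets within a limitation do.

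What nitrogen limitation changed against glucose limitation was asked with both limitations in all 3 sets. Genes for poor nitrogen sources rose: DAL5 (YJR152W, chromosome X, 719666 to 721297, build R64), which imports allantoate, rose by 7.07 ± 0.12 (SE, log2; adjusted p = 1.3e-28). DAL5 measured 3719 ± 277, 2089 ± 367 and 3817 ± 241 CPM under N-lim in the DASGIP tagged, MC tagged and MC untagged sets, against 25.5 ± 1.71, 22.4 ± 2.36 and 21.3 ± 1.00 CPM under Glu-lim. The oligopeptide transporter OPT2 rose by 7.19 ± 0.10 (adjusted p = 1.56e-30), the regulator DAL80 by 7.12 ± 0.15, the amino acid permease GAP1 by 5.06 ± 0.11 and the ammonium permease MEP2 by 4.71 ± 0.12. These cultures had 6% glucose against 0.75% under Glu-lim, so the comparison cannot separate scarce nitrogen from ample glucose. The low-affinity hexose transporters HXT3 (5.85 ± 0.11) and HXT1 (3.87 ± 0.24) rose, with pyruvate decarboxylase PDC5 at 5.96 ± 0.10 and the ester synthase EEB1 at 5.42 ± 0.08. Among the largest falls the alcohol dehydrogenase ADH2 (YMR303C, chromosome XIII, 873291 to 874337) changed by -7.42 ± 0.13 (adjusted p = 2.61e-28), RGI2 by -7.57 ± 0.24, the spore wall gene SPS100 by -7.02 ± 0.13 and SPG4 by -6.55 ± 0.20. The desiccation genes GRE1 (-7.84 ± 0.25) and SIP18 (-6.66 ± 0.27) and the transporter HXT5 (-4.23 ± 0.16) fell as well.

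By lists, 18 of 19 gluconeogenesis and glyoxylate genes fell under N-lim and 1 rose (camera adjusted p = 5.78e-26; adjusted p = 0.0209 with an estimated correlation, 18 fell adjusted over the list alone), among them the acetyl-CoA synthetase ACS1 at -5.94 ± 0.15 and the activator SIP4 at -3.53 ± 0.07. Of 26 genes under nitrogen catabolite repression, 19 rose and 5 fell (2.79e-22; 0.00451 with an estimated correlation, 19 rose adjusted over the list alone). All 7 genes specific to MATa cells rose (5.01e-16; 0.00768 with an estimated correlation, 7 adjusted over the list alone), led by the pheromone genes MFA2 (4.02 ± 0.09) and MFA1 (3.92 ± 0.10) and the receptor STE2 (2.77 ± 0.09), while the list of MATalpha genes was not called (0.312). Meiosis genes fell in 11 of 13 and rose in 1 (0.0253; adjusted p = 0.255 with an estimated correlation, 11 and 1 adjusted over the list alone). That call ended with only the libraries compared (0.0593). Gluconeogenesis, nitrogen catabolite repression and MATa were the only 3 of 21 called lists that held with an estimated correlation. All 17 heat shock genes fell (5.07e-10; adjusted p = 0.255 with an estimated correlation, 17 adjusted over the list alone), with the chaperone SSA3 at -5.01 ± 0.14. All 8 genes of the mitochondrially encoded list fell (0.000232; adjusted p = 0.255 with an estimated correlation, 8 adjusted over the list alone), with COX3 at -1.95, and the 8 histone genes, whose near-identical pairs are uncertain, rose (1.5e-05; adjusted p = 0.255 with an estimated correlation, 8 adjusted over the list alone). In all, 4741 of 6612 genes were called (2266 higher, 2475 lower), 886 of them by at least 2-fold (276 higher, 610 lower).

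What ethanol as the carbon source changed against glucose limitation was asked in the same way. Genes that make sugar from smaller molecules rose under Et-lim: PCK1 (YKR097W, chromosome XI, 631152 to 632801), which starts gluconeogenesis, rose by 5.82 ± 0.20 (adjusted p = 2.07e-20), from 34.4 ± 5.73, 43.1 ± 1.38 and 55.1 ± 11.6 CPM in the DASGIP tagged, MC tagged and MC untagged sets to 2364 ± 305, 2716 ± 120 and 2307 ± 270 CPM. ICL1 (YER065C, chromosome V, 285241 to 286914) of the glyoxylate cycle rose by 4.58 ± 0.09 (adjusted p = 5.93e-26), its partner MLS1 by 4.28 ± 0.09, FBP1 by 4.18 ± 0.12 and MDH2 by 3.79 ± 0.11. Chitin deacetylase CDA2 (6.00 ± 0.19), the acetate transporter ADY2 (4.57 ± 0.18) and DPA10 (4.34 ± 0.12) were the other genes of largest rise. Among those of largest fall were SPS100 (-5.71 ± 0.12), the sterol-binding gene HES1 (-4.45 ± 0.20), PBI1 (-4.27 ± 0.11), the cell wall gene PIR3 (-3.48 ± 0.21) and, in families with near-identical members, PAU2 (-4.66 ± 0.17) and TDH1 (-3.23 ± 0.16).

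Of the gluconeogenesis list 17 of 19 genes rose (camera adjusted p = 2.16e-56; 0.000603 with an estimated correlation), as did all 15 of the citric acid cycle (2.21e-34; 0.0012) with FUM1 at 1.66, all 20 nuclear respiratory chain genes (6e-22; 0.0293) with COX12 at 0.97, and all 12 of ATP synthase (3.21e-15; 0.0307) with ATP5 at 0.83. Adjusted over the list alone these counts were 17, 15, 20 and 12. Ergosterol synthesis fell in 18 of 23 genes (1.51e-15; 0.0229 with an estimated correlation, 18 adjusted over the list alone), with ERG11 at -1.72 and ERG1 at -1.54. Glycolysis and fermentation fell in 18 of 21 (1.96e-14; 0.0307 with an estimated correlation, 18 adjusted over the list alone), with ADH1 at -1.58 and PDC1 at -1.22. All 17 heat shock genes fell (9.6e-14; adjusted p = 0.109 with an estimated correlation, 17 adjusted over the list alone), and so did 28 of 30 ribosome biogenesis genes (4.2e-05; adjusted p = 0.541 with an estimated correlation, 28 adjusted over the list alone). The cytochrome genes CYC1 (0.93) and CYT1 (0.71) rose and CYC7, a form used at low oxygen, fell by 2.13. Of 6612 genes 3918 were called (2022 higher, 1896 lower), 368 by at least 2-fold (135 higher, 233 lower), and 8 of the 22 lists called held with an estimated correlation. Of the lists for cell types MATa genes rose in 6 of 7 (0.00108, adjusted p = 0.191 with an estimated correlation, 6 adjusted over the list alone) and MATalpha genes were not called (0.938). Meiosis genes rose in 6 of 13 and fell in 2 (0.045; adjusted p = 0.191 with an estimated correlation, 6 and 2 adjusted over the list alone). The meiosis call ended without DASGIP tagged Et-lim replicate 1 (0.0613), MC tagged Et-lim replicate 1 (0.0509), MC tagged Glu-lim replicate 1 (0.066) or MC untagged Et-lim replicate 1 (0.0555). It also ended with DESeq2 (0.0664), with a filter of 5 CPM (0.0504), with only the libraries compared (0.0719) and with libraries thinned to equal depth (0.0563).

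Oxygen and glucose together limited growth in the OxGlu-lim cultures, and their comparison with Glu-lim asked what changed with scarce oxygen. These cultures also had 1% glucose against 0.75% under Glu-lim, so changes cannot be put down to oxygen alone. Cell wall mannoproteins of low oxygen rose: TIR1 (YER011W, chromosome V, 175248 to 176012) by 6.52 ± 0.15 (adjusted p = 3.9e-25), to 394 ± 44.2 CPM in the DASGIP tagged and 413 ± 33.8 CPM in the MC tagged set, and DAN1 by 6.14 ± 0.15. The translation factor ANB1 rose by 5.98 ± 0.18, the sterol importer AUS1 by 3.42 ± 0.06 and the haem enzyme HEM13 by 2.78 ± 0.07. INA1 (4.35 ± 0.09), the adhesin FLO11 (4.26 ± 0.20; adjusted p = 1.09e-17) and HXT6 (5.28 ± 0.30), whose reads HXT7 can share, were also among the largest. The rise of FLO11 was 5.73 in the DASGIP tagged and 5.17 in the MC untagged set but 1.87 in the MC tagged set, where it was 1.21 (adjusted p = 0.00506) without MC tagged OxGlu-lim replicate 3. ADH2 (-6.56 ± 0.13), SPS100 (-6.58 ± 0.13), GRE1 (-5.22 ± 0.22), the aminotransferase ARO9 (-4.90 ± 0.20), the chaperone HSP26 (-4.42 ± 0.25) and ADY2 (-4.01 ± 0.19) fell furthest.

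All 15 hypoxic genes rose (camera adjusted p = 1.19e-31; 9.32e-06 with an estimated correlation, 15 adjusted over the list alone). Iron uptake rose in 12 of 15 genes and fell in 2 (6.86e-09; 0.0382 with an estimated correlation, 12 rose adjusted over the list alone), with the mannoproteins FIT2 (4.01 ± 0.11) and FIT3 (3.24 ± 0.13) and the mRNA decay factor TIS11 (2.16 ± 0.09). All 7 MATa genes rose (1.2e-08; 0.0400 with an estimated correlation, 7 adjusted over the list alone), with MFA2 at 2.16. Neither MATalpha (0.674) nor meiosis genes (0.577) were called. Gluconeogenesis fell in 15 of 19 genes and rose in 2 (3.04e-22; 0.0247 with an estimated correlation, 15 fell adjusted over the list alone), and the osmotic response fell in 8 of 12 (2.59e-06; 0.0155 with an estimated correlation, 8 adjusted over the list alone). These were the 5 of 17 called lists that held. All 13 peroxisome genes fell (1.2e-08; adjusted p = 0.234 with an estimated correlation, 13 adjusted over the list alone), with CTA1 at -2.87, and so did 19 of 20 respiratory chain genes (0.000292; adjusted p = 0.45 with an estimated correlation, 19 adjusted over the list alone). CYC7 rose by 1.56 while CYC1 changed by -0.57 and CYT1 by -0.77. Of 6612 genes 4311 were called (2175 higher, 2136 lower), 704 by at least 2-fold (339 higher, 365 lower).

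**Figure D2:**
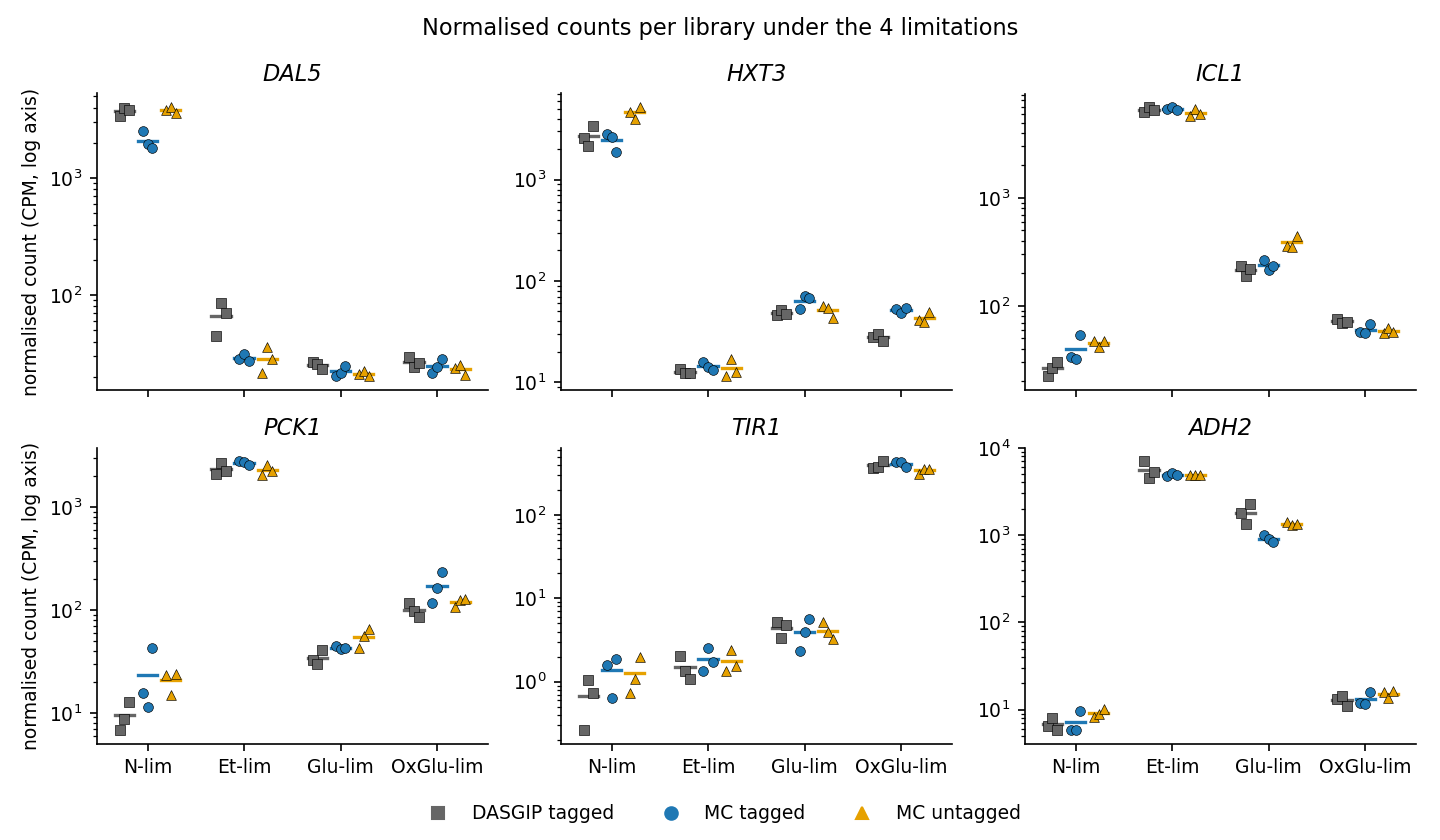
CPM on TMM-scaled library sizes (log y axis) of DAL5, HXT3, ICL1, PCK1, TIR1 and ADH2 in each library (points) by limitation and set, with a horizontal line at each group mean. DAL5 and HXT3 were high under N-lim, ICL1 and PCK1 under Et-lim and TIR1 under OxGlu-lim, in all 3 sets.

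Whether small vessels give the same response to a limitation as 1 L vessels was asked by comparing fold changes between sets, which share no libraries. The response of DAL5 to N-lim was 7.19 in the DASGIP tagged, 6.55 in the MC tagged and 7.48 in the MC untagged set, that of ICL1 to Et-lim 4.93, 4.82 and 3.98, that of PCK1 6.10, 5.98 and 5.39, and that of TIR1 to OxGlu-lim 6.47, 6.71 and 6.38. Across 6612 genes, which are not independent of each other, Pearson's r between MC tagged and DASGIP tagged fold changes was 0.818 for N-lim, 0.808 for Et-lim and 0.806 for OxGlu-lim, with jackknife SE of 0.0331, 0.0523 and 0.0499 over libraries, and Spearman's rho was 0.753, 0.730 and 0.650. Without DASGIP tagged Et-lim replicate 1 the r for Et-lim was 0.753. Between the MC tagged and MC untagged sets r was 0.764, 0.717 and 0.763 (jackknife SE 0.0381, 0.0723 and 0.0641). Values for the MC untagged set include the 12 displaced small RNA lines as deposited, which stand 2 places apart between its N-lim and Glu-lim libraries. Of genes called in both the MC tagged and DASGIP tagged sets, 97.1% (2546 of 2622), 99.4% (1567 of 1577) and 97.1% (1772 of 1824) had the same sign. For the MC tagged and MC untagged sets the shares were lower, at 90.9% (2331 of 2564), 95.3% (1434 of 1505) and 90.6% (1869 of 2063). Between the DASGIP tagged and MC untagged sets, which differ in both vessel and strain, r was 0.860, 0.760 and 0.844, above that of the MC tagged and DASGIP tagged sets for N-lim and OxGlu-lim. In all 3 sets 996 genes were higher under N-lim and 1012 lower (144 and 173 expected of independent lists), 556 higher and 501 lower under Et-lim (52.8 and 41.6 expected), and 681 higher and 762 lower under OxGlu-lim (94.1 and 98.7 expected). Between sets 301 genes had opposite calls for N-lim, 98 for Et-lim and 263 for OxGlu-lim.

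**Figure D3:**
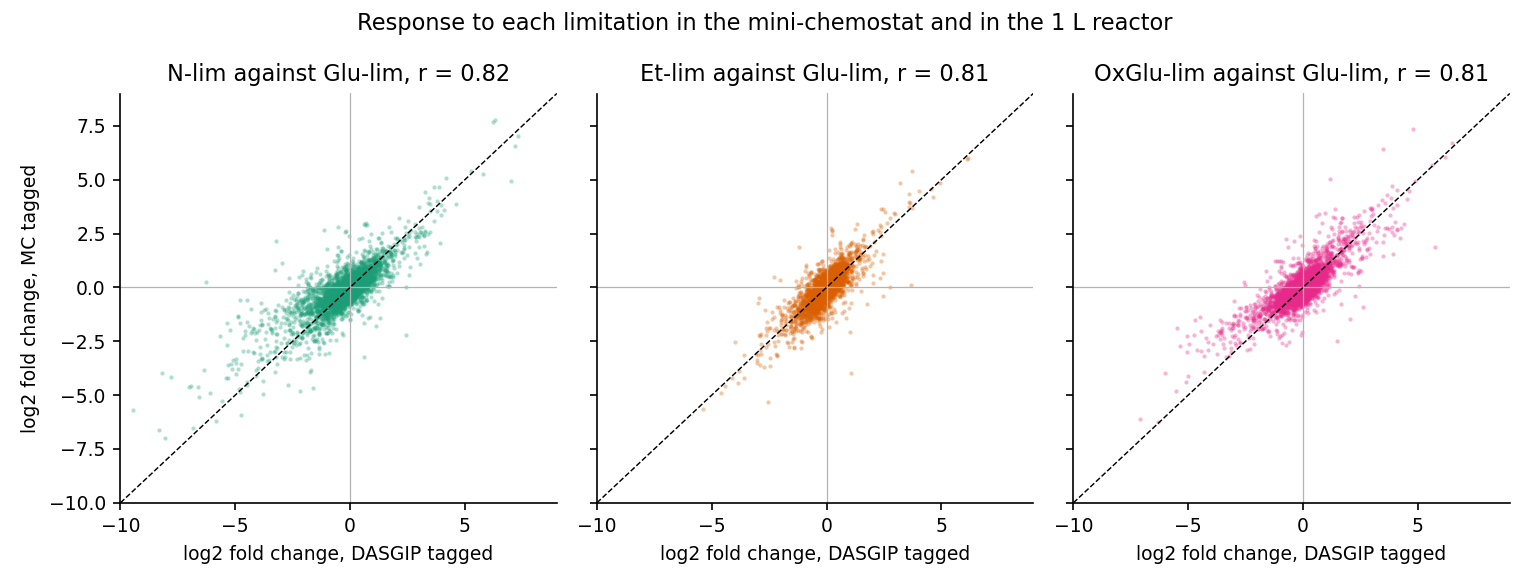
Log2 fold change of each limitation against Glu-lim in the MC tagged set (y axis) against that in the DASGIP tagged set (x axis), a point per gene, with a dashed line of equal change. Pearson's r across genes was 0.82 for N-lim, 0.81 for Et-lim and 0.81 for OxGlu-lim.

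The direct comparison of vessels set MC tagged against DASGIP tagged libraries, the same strain in both. Among the genes higher in the MC tagged libraries were SIP18 (YMR175W, chromosome XIII, 611016 to 611255), a desiccation protein, by 1.99 ± 0.20 (adjusted p = 1.25e-08), its relative GRE1 by 1.92 ± 0.18, the sodium pump ENA1 by 1.69 ± 0.26, the glycerol importer STL1 (YDR536W, chromosome IV, 1508005 to 1509714) by 1.68 ± 0.13 (adjusted p = 1.09e-10), HXT5 by 1.62 ± 0.13 and the catalase CTT1 by 1.54 ± 0.19. STL1 under Et-lim measured 171 ± 19.5 CPM in the DASGIP tagged, 1380 ± 105 CPM in the MC tagged and 1110 ± 116 CPM in the MC untagged libraries. SIP18 did not follow the vessel in this way, since under N-lim it was also 3.52 ± 0.46 higher in the MC tagged than in the MC untagged libraries, grown in the same kind of vessel. Genes of daughter cell separation were lower in the MC tagged libraries: DSE1 by -0.94 ± 0.07 (adjusted p = 3.09e-11), AMN1 by -0.89 ± 0.06, DSE2 by -0.85 ± 0.06 and the regulator SFG1 by -0.92 ± 0.09. FLO11 (YIR019C, chromosome IX, 389572 to 393675) changed by -1.45 ± 0.18, GAP1 by -1.01 ± 0.08, MEP2 by -0.98 ± 0.09 and the mitochondrially encoded VAR1 by -0.94 ± 0.15. Under OxGlu-lim FLO11 was also lower in the MC tagged than in the MC untagged libraries, so its change there did not follow the vessel alone.

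All 9 daughter separation genes fell (camera adjusted p = 5.51e-29; 0.000515 with an estimated correlation, 9 adjusted over the list alone), and 9 of 12 osmotic response genes rose while 1 fell (1.98e-12; 0.000386 with an estimated correlation, 9 rose and 1 fell adjusted over the list alone), with GRE2 at 0.91 ± 0.09 and GPD1 at 0.75 ± 0.07. These 2 of the 11 lists called held with an estimated correlation. Both also moved the same way, by less, between the strains in MC vessels, so part of these changes may mark the MC tagged set. There all 9 daughter separation genes fell (median -0.33, against -0.83 for the vessels). Of the osmotic genes 5 rose and 0 fell (median 0.18 against 0.96, camera adjusted p = 0.0331, and 0.0635 with upper-quartile factors). Under Glu-lim, however, 4 osmotic genes were lower in the tagged strain and 1 higher. All 17 heat shock genes rose (1.27e-16; adjusted p = 0.130 with an estimated correlation, 17 adjusted over the list alone), with BTN2 at 0.86 ± 0.07. Within limitations 17 were called under N-lim, 15 under OxGlu-lim, 6 under Et-lim and 3 under Glu-lim, where the list was not called (0.195). Under N-lim the mean log2 CPM of the list was 6.11 to 6.27 in the MC untagged libraries, within the 5.94 to 6.33 of the DASGIP tagged libraries. The rise under N-lim thus marked the MC tagged set and did not follow the vessel alone. Nitrogen catabolite repression genes fell in 17 of 26 and rose in 1 (1.97e-09; adjusted p = 0.0618 with an estimated correlation, 18 adjusted over the list alone), with GLN1 at -0.41 ± 0.05. Of 137 cytosolic ribosomal protein genes, whose paralogs are uncertain, 58 fell and 6 rose (2.92e-06; adjusted p = 0.945 with an estimated correlation and 0.118 by fry). Under OxGlu-lim 87 of them were lower and 1 higher (1.03e-26; adjusted p = 0.491 with an estimated correlation). The other limitations had 4 or fewer called in either direction, and the difference between limitations was not tested for the list. Of the lists for cell types, MATa genes fell in 3 of 7 (0.0093; adjusted p = 0.488 with an estimated correlation, 3 adjusted over the list alone), and neither MATalpha genes (0.19) nor meiosis genes (0.774) were called. Within limitations MATa genes were lower under N-lim (camera adjusted p = 0.0155), where MATalpha (0.00677) and meiosis genes (0.00800) were higher. Under Glu-lim both MATa (0.00239) and meiosis genes (0.0108) were lower. None of these calls held with an estimated correlation (adjusted p of 0.123 to 0.398). The list of 8 mitochondrially encoded genes was not called in the mean (0.739), with 4 higher and 2 lower, a median of 0.25 and a mean of -0.08. Between the vessels 2273 of 6612 genes were called (1130 higher, 1143 lower), but only 56 by at least 2-fold (46 higher, 10 lower). Upper-quartile factors moved the split to 1396 higher and 837 lower, so the share of higher calls depends on the scaling.

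Within limitations the leading genes of the vessel comparison differed. Under N-lim SIP18 rose by 4.49 ± 0.50, TKL2 by 3.62 ± 0.43 and ENA1 by 4.73 ± 0.67, although ENA1 rose by 2.65 without MC tagged N-lim replicate 3 and was not called with only the libraries compared (adjusted p = 0.0674). PDC5 (-2.21 ± 0.14; adjusted p = 5.58e-12), the sulphur gene IRC7 (-1.57 ± 0.12) and DSE2 (-1.54 ± 0.12) fell. Under Et-lim STL1 (3.01 ± 0.25), the mannoprotein FIT1 (2.11 ± 0.23) and SNR40 (2.05 ± 0.32) rose, while VAR1 (-2.04 ± 0.31) and GAP1 (-1.65 ± 0.17) fell. The fall of the uncertain HXT6 there (-2.24 ± 0.63; adjusted p = 0.0171) was not called without DASGIP tagged replicate 3 (0.0563) or MC tagged replicate 1 (0.0681) or 3 (0.0671), with limma-voom (0.0599) or with libraries thinned to equal depth (0.0628). Glu-lim had STL1 at 1.75 ± 0.25, the methionine permease MUP1 at 1.62 ± 0.27 and BSC1 at 1.52 ± 0.21, against ADY2 at -2.02 ± 0.28, RGI1 at -2.30 ± 0.51 and HXT6 at -3.23 ± 0.53. Under OxGlu-lim SIP18 (3.03 ± 0.40), GRE1 (3.03 ± 0.36) and HXT5 (2.56 ± 0.26) rose, while FLO11 (-4.50 ± 0.33; adjusted p = 8.03e-11), SPS4 (-2.29 ± 0.25) and OPT2 (-2.14 ± 0.14) fell. FLO11 measured 405 ± 190 CPM in the DASGIP and 17.9 ± 11.3 CPM in the MC tagged libraries there. Calls numbered 1211 under N-lim, 782 under Et-lim, 1397 under Glu-lim and 1166 under OxGlu-lim. With only the libraries compared they numbered 287 under N-lim, 422 under Et-lim and 391 under OxGlu-lim. The Et-lim count was 466 without DASGIP tagged replicate 3, 474 without MC tagged replicate 1 and 483 without MC tagged replicate 3. The Glu-lim count was 838 without DASGIP tagged replicate 3, and the OxGlu-lim count was 737 or 764 without DASGIP tagged replicate 2 or 3 and 755 without MC tagged replicate 3. Higher calls were 609 of 1397 under Glu-lim and 589 of 1166 under OxGlu-lim, against 867 higher and 527 lower, and 760 higher and 456 lower, with upper-quartile factors.

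**Figure D4:**
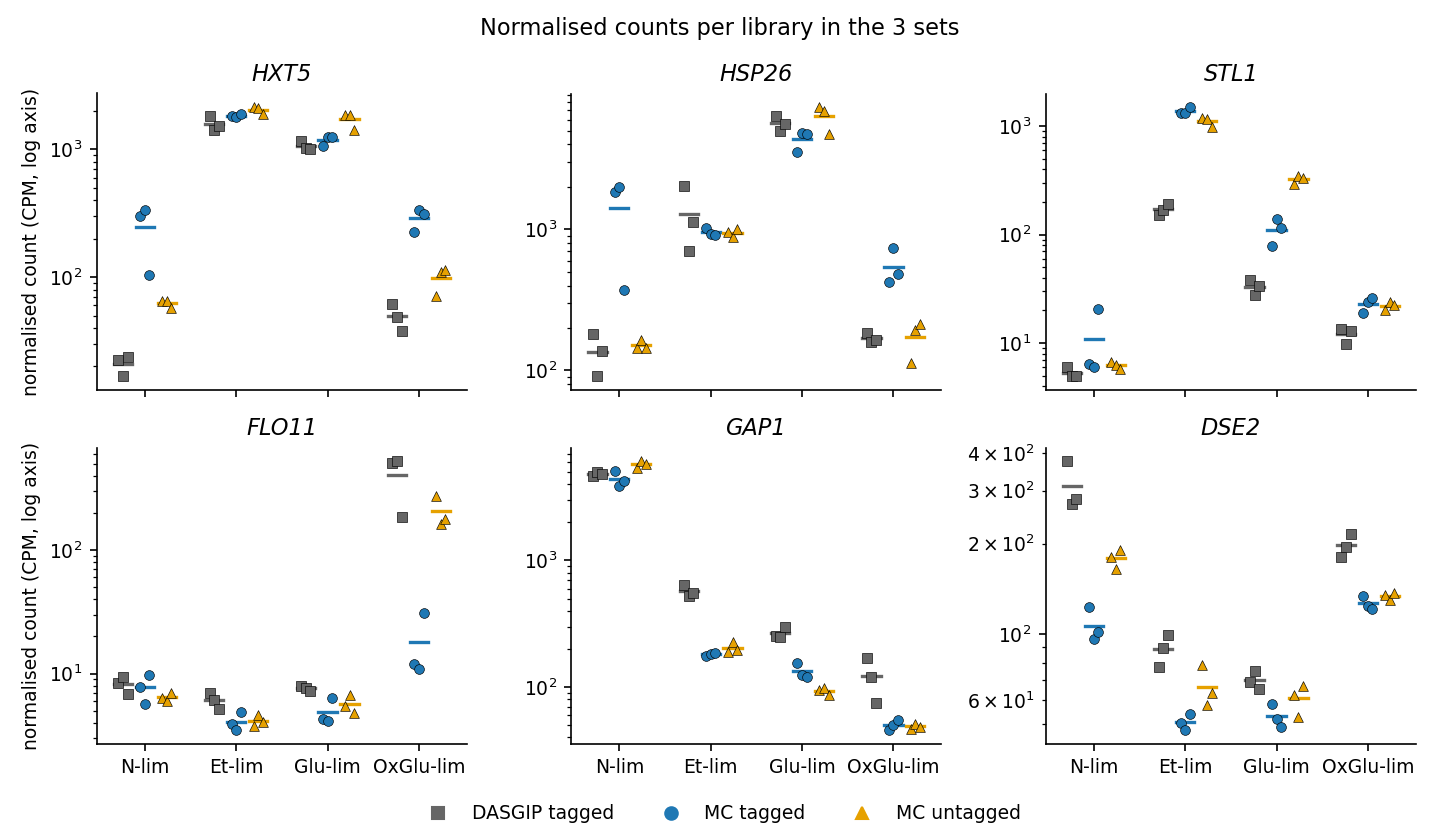
CPM on TMM-scaled library sizes (log y axis) of HXT5, HSP26, STL1, FLO11, GAP1 and DSE2 in each library (points) by limitation and set, with a horizontal line at each group mean. FLO11 under OxGlu-lim was lowest in the MC tagged set, and STL1 under Et-lim was lowest in the DASGIP tagged set.

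The strains were compared within the MC vessels, to see what differed in the strain with the tag on Hap1p. This comparison cannot separate the tag from any other difference between the strains. The tagged gene HAP1 (YLR256W, chromosome XII, 646415 to 650923), a regulator of respiratory and sterol genes that senses haem, changed by -0.12 ± 0.06 and was not called (adjusted p = 0.121). Over the mean of 4 limitations 1 of 11 Hap1 targets rose and 2 fell, the list was not called (camera adjusted p = 0.414), and adjusted over the list alone 1 rose and 3 fell. Within limitations targets moved both ways, and the list was called in none. Under N-lim 4 were higher and 1 lower (0.511), with 5 lower under Glu-lim (median -0.46; 0.0690), 3 lower under OxGlu-lim (0.645) and no target called under Et-lim (0.751). CYC1 (-0.13; adjusted p = 0.207), CYC7 (0.15; 0.620), CYB2 (0.06; 0.821) and CYT1 (0.11; 0.175) were not called, and the call of CTT1 (0.64; 0.0173) ended with limma-voom (0.0683). URA3 of uracil synthesis changed by -0.38 ± 0.06 (adjusted p = 8.25e-05). The old yellow enzyme OYE3 (YPL171C, chromosome XVI, 226169 to 227371) was higher in the tagged strain by 0.68 ± 0.11 (adjusted p = 7.02e-05), the chaperone gene BTN2 by 0.53 ± 0.07 (9.01e-06), and HES1 by 0.57 ± 0.19 (0.0377), which was 0.37 (0.172) without MC tagged N-lim replicate 3 and 0.49 (0.232) with limma-voom. Its call also ended, at adjusted p of 0.0506 to 0.0919, without MC tagged Et-lim replicate 1 or 2, Glu-lim replicate 2 or 3 or OxGlu-lim replicate 2, or without MC untagged Et-lim replicate 1 or 2, Glu-lim replicate 2 or 3 or N-lim replicate 2 or 3. The purine gene IMD2 (YHR216W, chromosome VIII, 554396 to 555967) was lower by -1.04 ± 0.10 (adjusted p = 6.88e-09). Among small RNA genes outside the displaced lines SNR47 (1.16 ± 0.17), SNR64 (1.14 ± 0.15) and SNR48 (0.79 ± 0.18) were higher and SNR190 (-1.18 ± 0.09; adjusted p = 1.28e-10) was lower. SNR71 (-7.15), SNR72 (-4.19) and SNR70 (-3.84) belong to the 12 displaced lines. Moved back, SNR71 came to -0.33 (0.0717), SNR72 to -0.30 (0.253) and SNR75 to -0.23 (0.218), none of them called, while SNR70 came to -0.35 (0.0137).

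Of the lists, 16 of 17 heat shock genes rose in the tagged strain (camera adjusted p = 1.09e-09; adjusted p = 0.372 with an estimated correlation, 17 adjusted over the list alone), with HSP26 at 1.09 ± 0.19 and HSP82 at 0.53 ± 0.09. Within limitations 16 were higher under N-lim and 12 under OxGlu-lim (adjusted p = 0.250 and 0.737 with an estimated correlation), and the difference between limitations was not tested for the list. Under Et-lim no gene of the list was called, and under Glu-lim 1 was higher and 1 lower, with a median of -0.40 (0.337). All 9 daughter separation genes fell (5.88e-08; adjusted p = 0.310 with an estimated correlation, 9 adjusted over the list alone), with EGT2 at -0.48 ± 0.07 and SCW11 at -0.42 ± 0.07, although under OxGlu-lim the list was not called (0.665). Ergosterol synthesis fell in 10 of 23 genes (5.22e-05; adjusted p = 0.372 with an estimated correlation, 13 adjusted over the list alone), with MVD1 at -0.32 ± 0.05 and ERG26 at -0.29 ± 0.04. In the mean the citric acid cycle rose in 8 of 15 (0.000116; adjusted p = 0.486 with an estimated correlation, 9 adjusted over the list alone), with SDH4 at 0.30 ± 0.05. Within limitations 12 of its genes were higher under N-lim and 7 under OxGlu-lim while 12 were lower under Glu-lim (median -0.44, 1.18e-07, adjusted p = 0.421 with an estimated correlation). By camera 16 of 36 lists were called. With an estimated correlation camera called 0, with 4 at an unadjusted p under 0.05, and fry called 14. In the mean the lists of MATa (0.13), MATalpha (0.632) and meiosis genes (0.488) were not called. Under N-lim MATa genes were lower in 7 of 7 (camera adjusted p = 3.59e-05, and 0.250 with an estimated correlation). Meiosis genes were higher there in 4 of 13 (0.0213, and 0.253 with an estimated correlation). Under Et-lim and Glu-lim none of these lists was called. Between the strains 1200 genes were called (554 higher, 646 lower, 11 of them displaced lines), only 23 by at least 2-fold, of which 9 were displaced lines. The split depended on scaling: 857 higher and 411 lower with upper-quartile factors, and 736 higher and 482 lower with library sizes without rRNA, tRNA and mitochondrially encoded lines.

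Within limitations the fewest genes were called between the strains under Et-lim. There 18 genes were called (11 higher, 7 lower; 744 at an unadjusted p under 0.05), of which 9 were displaced lines, and 4 were called without those lines. Of the others SNR69 rose by 1.34 ± 0.23 (adjusted p = 0.00201), SNR64 by 1.56 ± 0.30 (0.00729; 0.0531 without MC untagged Et-lim replicate 3) and CSN9 changed by -0.75 ± 0.13 (0.00258). The list of 8 mitochondrially encoded genes was lower in the tagged strain there (median -0.69; camera adjusted p = 4.14e-07; adjusted p = 0.616 with an estimated correlation), with none of its genes called, and their share of reads was 34.9 ± 2.86% against 43.3 ± 3.09%. DESeq2 called 94 (38 higher, 56 lower), and without MC untagged Et-lim replicate 2 edgeR called 69. N-lim gave 2144 calls (6 of them displaced lines), with SIP18 at 3.52 ± 0.46, HSP26 at 3.22 ± 0.40, HXT1 at -2.53 ± 0.38, SNR67 at -2.01 ± 0.27 and IMD2 at -2.01 ± 0.20. The decarboxylase ARO10 there rose by 2.94 ± 0.47, but by 1.11 without MC tagged N-lim replicate 3, and was not called with only the libraries compared (0.0562). Glu-lim gave 1491 calls (11 displaced lines), with MUP1 at 2.13 ± 0.28, DUG3 at 1.57 ± 0.13, AQR1 at 1.52 ± 0.24, SPO24 at -1.67 ± 0.24 and ICY1 at -1.64 ± 0.28. Of these 540 were higher and 951 lower, against 901 and 505 with upper-quartile factors and 759 and 614 with library sizes without rRNA, tRNA and mitochondrially encoded lines. The Glu-lim count was 858 without MC tagged replicate 1 and 875 or 988 without MC untagged replicate 1 or 2. OxGlu-lim gave 1592 calls (10 displaced lines), with VAR1 at 4.47 ± 0.38, SIP18 at 1.79 ± 0.37, YRO2 at 1.65 ± 0.28, FLO11 at -3.52 ± 0.32, SNR190 at -2.44 ± 0.19 and SNR4 at -2.03 ± 0.18, and 966 without MC tagged replicate 3 or 893 without MC untagged replicate 1. FLO11 and SIP18 led the vessel comparison too, which shares these MC tagged libraries.

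**Figure D5:**
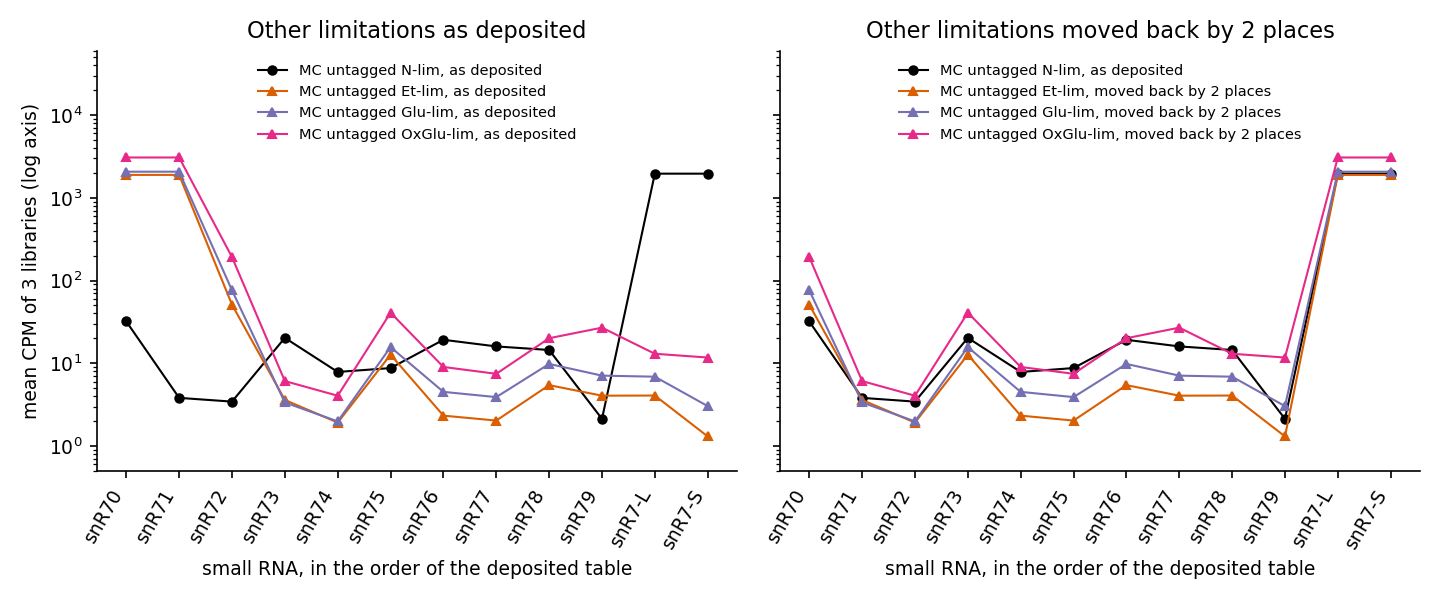
Mean CPM of 3 libraries (log y axis) of 12 small RNA genes in the order of the deposited tables (x axis) for the 4 limitations of the MC untagged set, as deposited (left) and with Et-lim, Glu-lim and OxGlu-lim moved back by 2 places (right). As deposited the 3 limitations run apart from N-lim, and moved back they follow it with r of 0.974, 0.979 and 0.964.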

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

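Both tests of displaced small RNA lines in this part were chosen after the result was seen. The vessel difference of several nutrient genes varied by limitation. The amino acid permease BAP2 changed by -1.51 ± 0.13 (SE, log2, MC tagged minus DASGIP tagged) under Et-lim and 0.83 ± 0.12 under OxGlu-lim, against 0.11 ± 0.13 under N-lim and -0.05 ± 0.12 under Glu-lim (adjusted p = 2.92e-09 by the F test over limitations). OPT2 changed by -2.14 ± 0.14 under OxGlu-lim alone (2.92e-09), with 0.23 ± 0.14 as its largest other value. PDC5 (9.12e-09) and the sulphur gene IRC7 (1.04e-07) fell most under N-lim, by 2.21 and 1.57. The hexose transporter HXT5 (7.08e-08) was 3.56 ± 0.28 higher under N-lim and 2.56 ± 0.26 higher under OxGlu-lim, against 0.21 ± 0.25 under Et-lim and 0.16 ± 0.25 under Glu-lim. The adhesin FLO11 (2.23e-07) changed by -4.50 ± 0.33 under OxGlu-lim and by -0.09 ± 0.35 under N-lim. What set these results apart was that 1593 of 6612 genes differed between limitations in this test. Of 100 ways to deal the libraries between the vessels within each limitation only the real 1 gave as many, and the highest other gave 457. These splits also break up any vessel difference shared by all limitations, so they cannot test whether it was equal across limitations.

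The strain difference varied by limitation in 3154 genes, among them all 12 displaced small RNA lines, where 1 of 100 splits, the real one, gave as many and the highest other gave 1626. Those splits have the same limit as for the vessels. TMT1, a methyltransferase gene, changed by -1.24 ± 0.09 under Glu-lim and 0.30 ± 0.09 under OxGlu-lim (adjusted p = 2.21e-09), and the helicase gene ECM32 by -0.84 ± 0.06 under Glu-lim (2.61e-08). The nucleotide kinase YNK1 (3.40e-08) was 0.67 ± 0.08 higher under N-lim and changed by -0.57 ± 0.08 under Glu-lim. KGD4 of the citric acid cycle (3.40e-08) was 0.90 ± 0.08 higher under N-lim and changed by -0.30 ± 0.07 under Glu-lim. DUG3 of glutathione breakdown (8.95e-08) was 1.57 ± 0.13 higher under Glu-lim. The mitochondrially encoded VAR1 (8.95e-08) was 4.47 ± 0.38 higher under OxGlu-lim and changed by -0.80 ± 0.31 under Et-lim. YNK1, KGD4, DUG3 and VAR1 were named after their values were seen, in place of displaced lines.

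The smallest p-values of that test belonged to small RNA genes: SNR7-S (1.24e-19), SNR7-L (4.34e-19), SNR71 (2.53e-17) and SNR70 (8.78e-15). SNR7-L, part of the splicing machinery, changed by -0.67 under N-lim but by 8.43, 7.36 and 6.98 under Et-lim, Glu-lim and OxGlu-lim. SNR71 changed by -0.67 under N-lim and by -9.31, -8.59 and -10.01 under the others. A candidate explanation is that 12 lines stand 2 places out of position in 9 MC untagged libraries: moved back, 0 of the 12 were called between the strains under Et-lim, where 9 were called as deposited. The shift was fitted to the tagged libraries of the same limitation, so a loss of strain calls was largely built in and cannot test this explanation. The untagged N-lim libraries took no part in that fit. A difference between the strains would keep the order of these RNAs within the untagged strain, but over the 12 genes Et-lim correlated with N-lim at r = -0.291 as deposited and 0.974 moved back, which argues against it. Moved back, 5 were still called under N-lim, 4 under Glu-lim and 9 under OxGlu-lim, and those remaining differences stay open.

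Heat shock genes were higher in the MC tagged set than in both other sets under N-lim and OxGlu-lim by camera at the preset correlation, but with an estimated correlation in none of the contrasts (adjusted p of 0.102 and 0.10 for the vessels, 0.250 and 0.737 for the strains). Under N-lim the MC tagged set also had lower MATa genes (camera adjusted p = 0.0155 for the vessels and 3.59e-05 for the strains). Meiosis genes were higher there (0.00800 and 0.0213). Neither list held with an estimated correlation (adjusted p of 0.125 to 0.368). Between the strains under OxGlu-lim 12 of the 17 heat shock genes were called. HSP26 measured 1407 ± 901 CPM under N-lim, against 136 ± 44.5 in the DASGIP tagged and 151 in the MC untagged set. A single divergent library as the source of the rise is argued against. In 6 of 6 MC tagged libraries the mean log2 CPM of the 17 genes exceeded every same-limitation library of the other sets. The ranges were 6.70 to 7.97 against 5.94 to 6.33 under N-lim and 7.23 to 7.67 against 6.15 to 6.87 under OxGlu-lim. The size of the N-lim rise rests mostly on replicates 1 and 2, at 7.86 and 7.97, against 6.70 in replicate 3. That replicate stood apart over all genes (chi-square per degree of freedom 123 and 155, against 24.1 between replicates 1 and 2). For slower growth of these cultures, the ribosome biogenesis list was lower in 3 of 4 contrasts where all 4 were predicted. With an estimated correlation it was called lower in none (adjusted p of 0.600, 0.705 and 0.737). Both contrasts of a limitation share its MC tagged libraries, so they are not separate tests. In a chemostat at steady state the feed sets the growth rate, and feed rates were not compared here, so slower growth stays open. A batch that ran with the MC tagged set cannot be told apart from the set itself, since the labels give none.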

How the results depend on the processing

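The fits without the 12 displaced small RNA lines, or with them moved back, were chosen after the result was seen. Named genes such as DAL5, ICL1, TIR1, STL1 and DSE2 kept their calls in every alternative fit of the 5 mean comparisons in which they were called. Over all alternatives 22491 values of named genes were made: where a call existed 15748 kept direction and call and 314 lost the call, 107 gained one and 10 reversed. For lists 2936 kept theirs, 96 lost it, 114 gained one and 0 reversed out of 6367. The 10 reversed values all came from displaced lines moved back: SNR7-L and SNR7-S went to -0.43 and -0.43 between the strains under Et-lim, to -0.87 and -0.87 under Glu-lim, to -0.91 and -0.91 under OxGlu-lim, and to -0.55 and -0.55 for N-lim against Glu-lim in the MC untagged set, and under Glu-lim SNR71 went to 0.67 and SNR72 to 0.23. The alternative's own construction is the cause.

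A threshold of 0.01 lowered the vessel counts to 1476 (mean), 639 (N-lim), 368 (Et-lim), 690 (Glu-lim), 600 (OxGlu-lim) and 774 (by limitation), the strain counts to 557, 1168, 11, 651, 877 and 1968 in that order, and Et-lim against Glu-lim in the DASGIP tagged set to 1337. Asking also for a 2-fold change left 56 genes for the vessels (N-lim 201, Et-lim 84, Glu-lim 106, OxGlu-lim 128) and 23 for the strains (N-lim 207, Glu-lim 84, OxGlu-lim 146). For the limitations, as mean and in the DASGIP tagged, MC tagged and MC untagged sets, it left 886, 930, 767 and 1108 (N-lim), 368, 339, 552 and 393 (Et-lim) and 704, 689, 631 and 993 (OxGlu-lim). Fits on only the libraries compared, which estimate the spread from fewer samples, gave 287 (N-lim), 422 (Et-lim), 391 (OxGlu-lim) and 1043 (by limitation) for the vessels, and 1212 (N-lim), 36 (Et-lim) and 871 (OxGlu-lim) for the strains. Spread also differed between groups: the median SD of log2 CPM was 0.147 in MC tagged N-lim and 0.139 in MC tagged OxGlu-lim. It was 0.0641 in MC tagged Et-lim and 0.0639 in MC untagged N-lim. The single model shares its estimate of the spread over all groups, and the cause of these moves was not tested.

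The strain count under Et-lim was 28 with libraries thinned to equal depth, 94 with DESeq2, and 4 without the displaced lines and 4 with them moved back; for the first 2 the cause was not tested. With an estimated correlation camera called 2 lists for the vessels, 0 for the strains, 3 for N-lim, 8 for Et-lim and 5 for OxGlu-lim, and fry called 32 for N-lim and 30 for OxGlu-lim, by tests that ask other questions. On genes above log2 CPM 5, r between MC tagged and DASGIP tagged fold changes was 0.863 for N-lim and 0.873 for Et-lim, and between MC tagged and MC untagged for Et-lim 0.803; the cause was not tested. No scaling moved the median of all genes by more than 0.0852.

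Leaving out each library in turn gave vessel counts of 466 to 986 under Et-lim, 838 to 1227 under Glu-lim and 737 to 1314 under OxGlu-lim, and strain counts of 12 to 69 under Et-lim, 858 to 1156 under Glu-lim and 893 to 1903 under OxGlu-lim. The lowest came without DASGIP tagged Et-lim replicate 3, DASGIP tagged Glu-lim replicate 3, DASGIP tagged OxGlu-lim replicate 2, MC tagged Glu-lim replicate 1 and MC untagged OxGlu-lim replicate 1, and the 69 without MC untagged Et-lim replicate 2. The correlation of MC tagged and DASGIP tagged fold changes for Et-lim ran from 0.753 (without DASGIP tagged Et-lim replicate 1) to 0.806. Of 8022 called values of named genes 224 lost the call with a library left out.

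Replicate numbers as a block, shared by all sets or within each, gave 2289 and 2337 calls for the vessels and 1159 and 1248 for the strains, and moved no count by more than 1.5 times. The numbers do not pair the libraries: in 3 of 66 pairs of groups did all 3 same-numbered deviations correlate above 0.1, and the median r was -0.00862. Replicates differed by more than counting noise, and thinning to equal depth moved no count of calls but that of the strains under Et-lim by more than 1.5 times.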

Other observations

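The test of the spread between Et-lim replicates and the split by kind of RNA were chosen after the result was seen. Transfer RNA genes were lower under N-lim than under Glu-lim, with 40 of 63 lower, 3 higher and a median log2 fold change of -1.14. These values rest on few reads. Group means of the tRNA share were 0.00488% to 0.00539% of reads under N-lim and 0.00593% to 0.00958% under Glu-lim. Only 63 of 299 tRNA lines passed the low-count filter. Mitochondrially encoded genes were lower under N-lim in 27 of 27, with a median of -1.67, and higher under Et-lim in 17 of 27 with 3 lower in the mean of the sets. Under Et-lim the MC tagged set had none called higher, 7 lower and a median of -0.03, and each of the other sets had 17 higher and none lower, a difference that was not tested. Small RNA genes outside the 12 displaced lines were lower under N-lim in 67 of 75, with a median of -0.86. Between the strains 35 of the 75 were lower in the tagged strain and 5 higher (median -0.29), and under OxGlu-lim 37 were lower and 4 higher (median -0.67), whereas under Et-lim none were called lower and 4 higher (median -0.24). Of these SNR190, which guides rRNA modification, measured 568 CPM in the DASGIP tagged, 606 in the MC tagged and 3284 ± 562 in the MC untagged set under OxGlu-lim. Between the vessels 31 of the 75 were higher in MC and 1 lower (median 0.23). HAP1 itself changed by -1.16 ± 0.06 under N-lim (adjusted p = 3.62e-16) and -0.79 ± 0.06 under Et-lim (8.67e-12) against Glu-lim, and was not called under OxGlu-lim (0.06 ± 0.06; 0.384).

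Few genes, 18, were called between the strains under Et-lim, where the median size of the log2 change was 0.104, against 0.214, 0.186 and 0.187 under N-lim, Glu-lim and OxGlu-lim. Named genes such as FLO11, HSP26 and SIP18, called between the strains under other limitations, were not among the calls there. Lower depth of the Et-lim libraries is argued against by the totals, which were the highest of each set's limitations at means of 20.2 M (MC tagged) and 21.2 M reads (MC untagged). With every library thinned to an equal total the lowest count of the other limitations was 1215, but depth outside mitochondrially encoded reads was not matched. A larger spread between replicates stays open: the median SD of log2 CPM, averaged over both groups, was 0.0785 under Et-lim against 0.106, 0.0794 and 0.106 under N-lim, Glu-lim and OxGlu-lim, but in the untagged group alone it was highest under Et-lim at 0.0928. Without MC untagged Et-lim replicate 2 the count was 69. A smaller effect of the tag on ethanol, or a batch shared by the Et-lim cultures of both strains, may explain the low count, and neither was tested.

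Other splits of the same libraries were counted for each number of calls. Of 100 splits for each mean comparison only the real 1 called as many genes, which argues against chance assignment. The calls were 2273 for the vessels (highest other 619), 1200 for the strains (839), 4741 for N-lim (3874), 3918 for Et-lim (3161) and 4311 for OxGlu-lim (3159). Splits that mix differing groups also widen the spread within them, and the median of the other splits was 0 in each comparison. Each split dealt the libraries anew within each limitation or set, so a split can keep the real assignment in some of them. A comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. There the vessels gave 1211 under N-lim (highest other 266), 782 under Et-lim (111), 1397 under Glu-lim (0) and 1166 under OxGlu-lim (172). The strains gave 2144 (143), 18 (0), 1491 (0) and 1592 (1) in the same order. In the DASGIP tagged, MC tagged and MC untagged sets N-lim gave 3692 (0), 3648 (20) and 4118 (0), Et-lim 2137 (112), 3082 (0) and 2497 (0), and OxGlu-lim 2936 (1), 2981 (4) and 3853 (1).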
